A study of Mus musculus with 12 samples.

How the data were processed

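The series profiled RNA of PDGFRα+ cells sorted from skeletal muscle and from bone of mice. PDGFRα is a growth factor receptor that marks mesenchymal stromal and progenitor cells. Knockout mice carried a tamoxifen-inducible Cre recombinase (PDGFRa-CreER) and a floxed estrogen receptor alpha gene (Esr1) on both alleles. Per the labels, muscle cells were gated as CD45-, CD31-, Vcam1- and PDGFRα+, and bone cells as CD45-, CD31- and PDGFRα+. The labels put 12 samples in 4 groups of 3, with control and knockout groups in each tissue. The control genotypes were mixed. Muscle control replicate 3 carried the Cre and 1 floxed Esr1 allele, bone control replicate 1 carried 2 floxed alleles without the Cre, and the remaining controls carried the Cre alone. The labels do not say whether replicates came from separate animals, so the authors' p-values may measure a partly technical spread.

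RNA was extracted with a column kit and libraries were made with the QuantSeq 3' mRNA-seq kit, per the labels' protocols. This chemistry reads the ends of polyadenylated transcripts, so a value reflects the 3' end of a gene and not its whole length. The aligner, the counting tool and the statistical test are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10.

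There are 2 tables, 1 per tissue, each with 25655 genes. The deposited log2 fold changes are the authors' knockout over control values, per the file headers, and positive values are higher in the knockout. The deposited p-values, FDR p-values and Bonferroni p-values are the authors' own, per the file headers. The group mean is a score taken from the deposited tables. It is the larger of the knockout and control means of a gene, per the file headers, which do not name its unit. The tables hold 48 further columns of per-library values, 4 kinds of value for 12 libraries. Their names are laboratory codes that match no label, so no column could be assigned to a sample, and no result here was computed from them. They were read in a comparison made outside the analysis, in which the group mean equalled, in every gene, the larger mean TPM, and equally the larger mean RPKM, of 1 split of the libraries of a tissue into 2 sets of 3. That split was not used to name samples or groups. The depth of each sample is therefore not given here, and no standard deviation, standard error or per-replicate value could be computed.

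The planned tests need columns assigned to groups by their labels and were not run for that reason. They were count-based tests of knockout against control within each tissue, of the interaction between tissue and genotype, and of muscle control against bone control, with gene list tests on the samples. The authors' comparison was used in their place. A gene was called at the authors' FDR under 0.05. Recomputing the Benjamini-Hochberg adjustment over the genes that kept an FDR returned the deposited FDR within 0.000995 in muscle and 0.000142 in bone. In muscle 13158 genes had a p and 7107 of them an FDR. In bone 10518 genes had a p and 8534 an FDR. Genes with a p and no FDR had a low group mean, with a median of 4.26 in muscle and 0.404 in bone.

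The gene lists, the thresholds and the rule for named genes were fixed before the data were examined. There were 37 lists with 572 entries, of which 568 matched a gene by its name, and 1 list of sex-linked genes was not tested. The rule named Esr1, Igfbp5 and Pdgfra in each tissue, the 10 genes of smallest p past FDR 0.05 in each direction, leaving out predicted genes, RIKEN clones and mitochondrial transcripts, and up to 4 members of smallest p of each list described. Where fewer than 5 genes passed in a direction, the 5 of smallest p were named with their values. Members of a list were tested with the authors' p, and the number under 0.05 was also counted with Benjamini-Hochberg adjustment over the list alone.

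Each p was turned into a z value carrying the sign of the fold change. Lists with at least 5 genes holding an FDR were tested against the other genes with cameraPR of limma 3.58.1 in R 4.3.3, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a tissue. The test is two-sided, and a list called lower is lower relative to the other genes of its table. A correlation cannot be estimated without samples, so a preset of 0.05 was run as an alternative. The median log2 fold change of a list was also placed among 10000 random lists matched on deciles of the group mean. On simulated z values, fibrillar matrix in muscle, and fibrillar matrix and neutrophil genes in bone, were shifted by 1.5 in 50 runs. The shifted lists were recovered in 100% of cases on the 7107 muscle genes and 95% on the 8534 bone genes, and 0.231% and 0.16% of lists sharing no member with them were called. The simulated z values were independent between genes and did not vary with the group mean. These rates therefore do not give the false-call rate in the data. Random muscle lists gave a matched p under 0.05 in 5% of 200 draws. These lists came from the same genes as the matched lists and their members were drawn at random. This rate therefore checks the computation only, and not lists whose members vary together.

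The difference between the tissues was tested per gene from the 2 fold changes and the spread that each p implies under a normal approximation. On simulated values for the 5773 genes, with 200 genes shifted by 6 standard errors, 99.8% were recovered and 4.95% of calls were false. The simulation drew values with the same standard errors that the test used, so these rates check the computation only. List differences were tested with cameraPR on the difference of the z values. Gene ontology terms given in the tables, with 10 to 200 genes, were tested in the same way. Medians were bootstrapped 2000 times for 95% intervals. The last 400 nt of the annotated transcripts of each called gene were compared with all transcripts by BLAST 2.17.0, keeping matches of at least 75 nt at 95% identity or more. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

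Of the 25600 Ensembl genes shared with GENCODE M21 on GRCm38, 564 (2.20%) had the same start and end in the tables. The positions in the tables were therefore not used, because their build is not named in the headers. Positions below are those of GENCODE M21 on GRCm38, matched by Ensembl identifier.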

Results

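The series compared PDGFRα+ mesenchymal cells of control mice and of mice labelled as conditional knockouts of Esr1, which encodes estrogen receptor alpha. Its stated aim was to find targets of Esr1 in muscle PDGFRα+ cells that bear on bone metabolism, and its title names IGFBP5. Muscle and bone each contributed 3 control and 3 knockout samples, profiled by 3' mRNA sequencing. Every fold change, p and group mean of a gene given below comes from the authors' deposited table for that tissue. The number of samples behind a fold change and the spread between replicates are not stated in that table. The p-values measure only the spread between samples, and list tests used a preset correlation between genes because an estimate needs values per sample.

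The targeted gene did not pass the test in either comparison. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614 on GRCm38) had a log2 fold change of 1.02 in muscle in the authors' deposited table (p = 0.404, FDR = 1.00). In bone the authors' deposited table gave it -2.69 (p = 0.245, FDR = 0.440). Its larger group mean was 45.6 in muscle and 75.9 in bone in the authors' deposited table. The labels do not say which exons are floxed, and a 3' tag counts the end of a transcript, which can outlast the deletion. These values therefore do not check the genotype labels. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), the gene of the sorting marker, did not pass either. The authors' deposited table gave it 0.50 in muscle (p = 0.139) and 1.06 in bone (p = 0.641).

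In muscle, the knockout samples had more transcript of a type I collagen chain and of a secreted IGF-binding protein. Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) was 2.42-fold higher in the authors' deposited table (log2 fold change 1.27, FDR = 0.00261). Igfbp5 (ENSMUSG00000026185, chromosome 1, 72857932 to 72874884) encodes a binding protein that holds insulin-like growth factors in the matrix. It was 2.34-fold higher in the authors' deposited table (log2 fold change 1.23, p = 1.26e-05, FDR = 0.0180), at a larger group mean of 1406. Its FDR passed the threshold and its Bonferroni p in the authors' deposited table did not (0.166, within a range of 0.00794 to 0.166 over the alternatives). Whether the study chose Igfbp5 from these samples is not given in the sources used here, but the series title names it. The call may therefore restate the study's own choice. In all, 9 genes passed the authors' FDR of 0.05 in muscle, 4 higher and 5 lower in the knockout, of 7107 genes with an FDR.

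The other called muscle genes were expressed at lower levels, apart from Lars2. Mxi1, a MAX-binding transcriptional repressor on chromosome 19, had a log2 fold change of 3.77 in the authors' deposited table (FDR = 0.0250). Osbpl2, a lipid-binding protein gene on chromosome 2, had 7.44 in the authors' deposited table (FDR = 0.00279) at a larger group mean of 58.4. Of the genes that fell, Lars2, the mitochondrial leucyl-tRNA synthetase gene on chromosome 9, had -1.32 in the authors' deposited table (FDR = 0.0377) at a larger group mean of 1836. Cnksr3, a scaffold protein gene, E2f5, a transcription factor gene, and L1cam, a cell adhesion gene, had -7.33, -7.17 and -7.11 in the authors' deposited table (FDR = 0.000467, 0.0281 and 0.0432). Their larger group means in the authors' deposited table were 65.6, 40.4 and 39.8. Fold changes of this size at such levels are fitted values that may stand for a group at or near 0, which was not checked here, so they are not estimates of size. Adjusted over all genes with a p, E2f5, Lars2 and L1cam did not pass (0.0521, 0.0697 and 0.0800). The transcript ends of L1cam share sequence with 7 other genes, so its value is uncertain. Chrd, which encodes the BMP antagonist chordin, had 6.81 in the authors' deposited table and Tpr, a nuclear pore gene, had -1.76, and neither passed (FDR = 0.0517 for both).

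The smallest p in muscle belonged to Gm2174, a predicted coding gene outside the rule for named genes, chosen after its values were seen. Gm2174 (ENSMUSG00000058932, chromosome X, 56447965 to 56448366) was 62.5-fold lower in the authors' deposited table (log2 fold change -5.97, FDR = 2.05e-14), at a larger group mean of 253. Its transcript shares 97.2% and 97.7% identity over 394 nt with C330021F23Rik and Gm5148, so its reads may be split among copies. In bone the authors' deposited table gave Gm2174 a log2 fold change of -4.59 (p = 0.00344, FDR = 0.0784), which did not pass.

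As lists, the matrix genes were higher in muscle knockout samples at the preset correlation of 0.01. Of 26 fibrillar matrix genes with an FDR, 1 rose, none fell and 25 did not pass, and 4 passed when adjusted over the list alone. The list was higher than other genes (median log2 fold change 0.47, cameraPR adjusted p = 2.31e-06), and 21 of its 26 members had a positive value in the authors' deposited table. Beside Col1a2, the smallest p belonged to Col14a1 (1.28), Col1a1 (0.86) and Loxl1, a collagen cross-linking enzyme gene (1.32), with FDR of 0.119, 0.204 and 0.232 in the authors' deposited table. Matrix proteases (16 genes, 0 passing, 2 adjusted over the list alone) were higher as a list (median 0.38, adjusted p = 0.0101). Its members of smallest p were Mmp19 (4.47), Mmp13 (8.90), Mmp14 (0.73) and Ctsb (0.71), none passing in the authors' deposited table. Mmp13 had a larger group mean of 24.8, so its value may stand for a group at or near 0. Basement membrane genes (12 genes, 0 passing, 0 adjusted over the list alone) were higher as a list (median 0.50, adjusted p = 0.0183), with Nid1 at 0.70 in the authors' deposited table (p = 0.0355). With the preset correlation at 0.05, the adjusted p was 0.000885 for fibrillar matrix and 0.0634 for each of the other 2 lists. Against random lists matched on the group mean it was 0.0196 for fibrillar matrix, 0.166 for matrix proteases and 0.130 for basement membrane. Only the fibrillar matrix call held in both.

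The IGF axis list held Igfbp5 and was higher in muscle knockout samples. It was tested with Igfbp5 in it, so its result is not separate from the Igfbp5 call. Of 13 members with an FDR, 1 rose and 12 did not pass, and 2 passed when adjusted over the list alone (median 0.40, cameraPR adjusted p = 0.0184). At a preset correlation of 0.05 its adjusted p was 0.0634, and against random lists matched on the group mean it was 0.237, so the call did not hold there. The other member with the smallest p was Igf1, the growth factor itself, at 1.07 in the authors' deposited table (p = 0.00366, FDR = 0.268). Igfbp3 had 0.67 and Igfbp7 0.40 in the authors' deposited table, and neither passed. The list of known estrogen receptor targets did not pass (10 genes, 0 passing, 2 adjusted over the list alone, median 0.20, adjusted p = 0.336), and 8 of its members had a positive value in the authors' deposited table. Nrip1, a receptor corepressor gene, had -3.13 in the authors' deposited table (p = 0.00216, FDR = 0.232), and Igf1 had 1.07 (p = 0.00366) and Ctsd 1.28 (p = 0.0464).

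Inflammatory and glucocorticoid response genes were lower in muscle knockout samples as lists at the preset correlation of 0.01. Inflammatory cytokine genes (15 genes, 0 passing, 2 adjusted over the list alone) were lower as a list (median -0.41, cameraPR adjusted p = 0.0161). The chemokine gene Ccl7 had -1.07 and Tnfaip6 -0.87 in the authors' deposited table, with p of 0.00597 and 0.00578. Glucocorticoid response genes (9 genes, 0 passing, 0 adjusted over the list alone) were lower as a list (median -0.48, adjusted p = 0.0222). The metallothionein gene Mt2 had -0.70 and Tsc22d3 -1.47 in the authors' deposited table, with p of 0.0202 and 0.0252. At a preset correlation of 0.05 the adjusted p was 0.0634 for both lists. Against random lists matched on the group mean it was 0.130 for inflammatory cytokine genes and 0.201 for glucocorticoid response genes. Neither call held in these 2 alternatives.

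Markers of other cell types were measured in the same muscle table. The erythroid list was lower (5 genes, 0 passing, 2 adjusted over the list alone, median -0.99, cameraPR adjusted p = 5.98e-05), in the comparison in which the matrix and IGF lists were higher. Hba-a2, an alpha globin gene, had -1.41 in the authors' deposited table at a larger group mean of 1607, and Alas2 had -5.64 at 37.7. Most members of this list were globin genes, which may vary together. A preset correlation of 0.01 can then be too low and the p of the list too small. Mural and smooth muscle genes did not pass (11 genes, median 0.49, adjusted p = 0.0508). Mesenchymal progenitor genes did not pass (16 genes, median 0.24, adjusted p = 0.111).

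**Figure D1:**
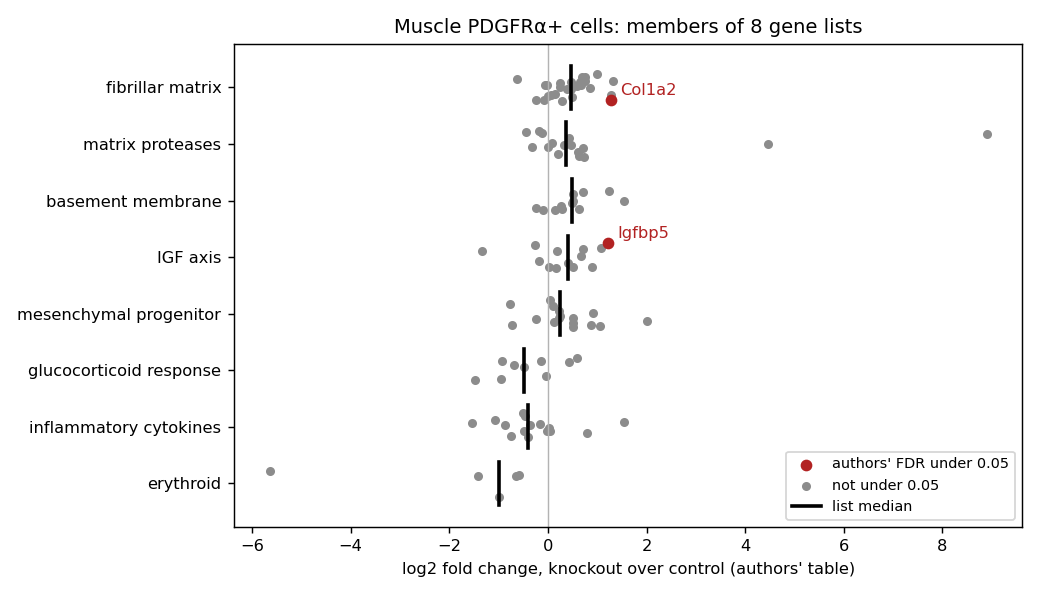
Each point is a gene of a fixed list in muscle PDGFRα+ cells, placed by its log2 fold change, knockout over control, in the authors' deposited table; vertical position within a list is arbitrary, red marks the authors' FDR under 0.05 and black bars are list medians. The fibrillar matrix median was 0.47 and the erythroid median -0.99, and Col1a2 and Igfbp5 are the marked genes.

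In bone, the knockout samples had more transcript of lactoferrin, a neutrophil granule protein. Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), which is also on the list of estrogen receptor targets, had a log2 fold change of 7.45 in the authors' deposited table (FDR = 0.000229), at a larger group mean of 279. Only 3 of 8534 genes passed the authors' FDR of 0.05. Hmgn2, a nucleosome-binding protein gene on chromosome 4, had 12.48 in the authors' deposited table and Pigk, a GPI-anchor transamidase gene on chromosome 3, had -8.14 (FDR = 0.0289 for both). The transcript ends of Hmgn2 share sequence with 13 other genes, so its value is uncertain. At an FDR of 0.1 the count was 2751, and 1253 of these genes share an FDR of 0.0784 in the authors' deposited table. The next higher genes by p were Mmp8, the neutrophil collagenase gene (12.17), S100a9 (3.06) and Retnlg (4.40). The next lower genes were Emp2 (-10.88), Tmem129 (-7.79), Cpt2 (-10.20) and Golm1 (-10.22). None of them passed in the authors' deposited table (FDR = 0.0784 for each). The largest bone fold changes, such as those of Hmgn2, Mmp8 and Emp2, may stand for a group at or near 0. That was not checked here, so they are not estimates of size. Igfbp5 did not pass in bone, with 0.80 in the authors' deposited table (p = 0.554, FDR = 0.764).

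Neutrophil genes were higher in bone knockout samples as a list. Of 10 members, 1 rose and 9 did not pass, and 7 passed when adjusted over the list alone (median log2 fold change 2.99, cameraPR adjusted p = 0.00160). All 10 had a positive value in the authors' deposited table. The calprotectin genes S100a8 and S100a9 had 2.88 and 3.06 in the authors' deposited table at larger group means of 6106 and 2846. Elane, an elastase of early granules chosen after its values were seen, had 0.07 in the authors' deposited table (p = 0.974). Chondrocyte genes were lower relative to other genes (13 genes, 0 passing, 0 adjusted over the list alone, median -1.11, adjusted p = 0.00354). Col9a1 had -2.69, Col2a1 -1.11 and Prg4 -0.94 in the authors' deposited table, none passing. Fibrillar matrix genes were lower relative to other genes (23 genes, 0 passing, 0 adjusted over the list alone, adjusted p = 0.0327), with a median of -0.89 and a mean of 0.23. The signs of the median and the mean differ because some members had large positive values. Its members of smallest p were higher, with Loxl1 at 9.39 and Postn at 7.89 in the authors' deposited table. Their larger group means were only 14.6 and 5.04. At group means above 10 to 20 and above 5 to 10, 68.6% and 84.9% of all bone genes were higher. The adjusted p of fibrillar matrix was 0.249 at a preset correlation of 0.05 and 0.173 with genes of a group mean of at least 50, so this call did not hold. That of chondrocyte genes was 0.0313 and 0.0418 in these settings. Against random lists matched on the group mean it was 0.102, so this call did not hold in every alternative.

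The estrogen receptor targets did not pass in bone as a list (12 genes, 1 rose, 11 not passing, 3 adjusted over the list alone, median 1.64, adjusted p = 0.815), and Ltf was the member that rose.

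Blood cell transcripts dominated the bone table. Hba-a2 had the highest larger group mean of all genes in the authors' deposited table, 263063, against 8.60 for Pdgfra. The 4 globin genes made up 58.4% of the summed larger group means in bone and 0.338% in muscle, from separate tables whose normalization is not given in the sources used here. The erythroid list did not pass (10 genes, median 0.78, cameraPR adjusted p = 0.980), nor did the macrophage list (16 genes, median 2.42, adjusted p = 0.532). With genes of a group mean of at least 50 alone, both lists were higher than other genes. The cameraPR adjusted p was then 0.0169 for macrophage genes and 0.0587 for erythroid genes. Against random lists matched on the group mean the erythroid adjusted p was 0.129. A rise of erythroid genes is therefore neither called nor excluded.

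**Figure D2:**
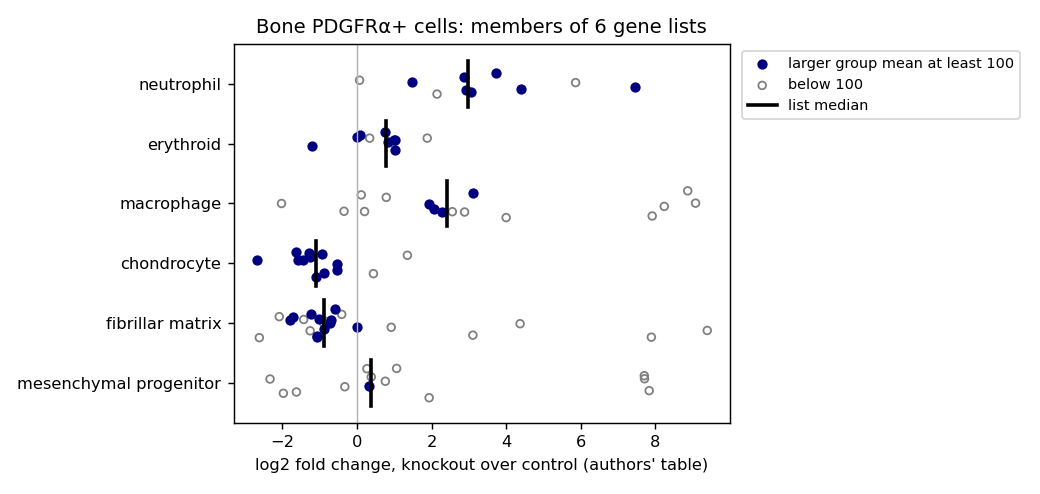
Each point is a gene of a fixed list in bone PDGFRα+ cells, placed by its log2 fold change, knockout over control, in the authors' deposited table; filled points have a larger group mean of at least 100 and black bars are list medians. All 7 filled neutrophil genes lie above 0 and all 11 filled chondrocyte genes below it.

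The bone fold changes were skewed towards higher values at low expression. Of 10518 genes with a p, 69.7% were higher in the knockout in the authors' deposited table, with a median log2 fold change of 2.51. Among 5455 genes with a larger group mean of at most 10, 84.3% were higher. Among 915 genes with a larger group mean above 50 to 100 the lean was the opposite, with 38.3% higher and a median of -0.50. Among 738 genes with a larger group mean of at least 100, 51.6% were higher, with a median of 0.03. In muscle, 53.5% of 13158 genes were higher and the median was 0.12.

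**Figure D3:**
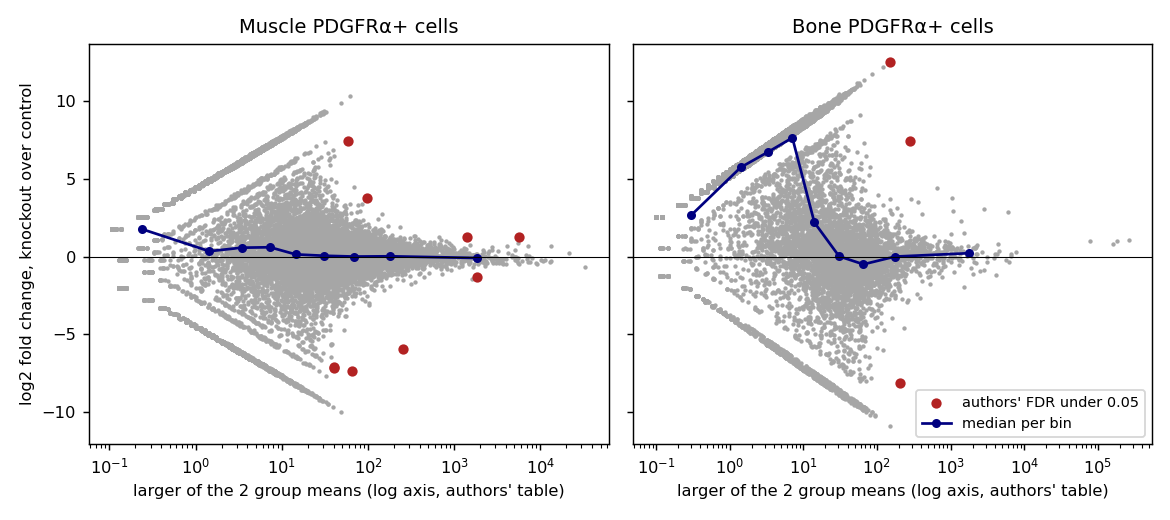
The log2 fold change, knockout over control, of each gene is plotted against the larger of its 2 group means on a log axis, both from the authors' deposited table, for muscle and bone; red points passed the authors' FDR of 0.05 and blue points are medians of bins of the group mean. In bone the median was 7.63 at group means above 5 to 10, 0.02 above 20 to 50 and -0.50 above 50 to 100, and in muscle it was 0.60 at the first and 0.05 at the second of these levels.

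The effects of the knockout in the 2 tissues were compared gene by gene. Across 9598 genes with a p in both, the fold changes in the authors' deposited table were uncorrelated (Pearson r = 0.0161, Spearman rho = 0.0255, across genes, which are not independent replicates). No gene was called in both tissues. At p under 0.05, 175 genes were higher in both, where independent lists would share 147 (exact hypergeometric p = 0.00309, genes not being independent), and 22 were lower in both, where they would share 16.1 (exact hypergeometric p = 0.0835). That expectation treats all genes as equally likely to reach p under 0.05. The share that did was 0% at group means of 1 or less in both tissues. Above 5 to 10 it was 33.4% in muscle and 67.4% in bone. The excess therefore does not show a shared effect. No difference between the tissues passed at an adjusted p of 0.05 in a normal-approximation test of the 2 effects, among 5773 genes, of which 1512 had an unadjusted p under 0.05. The Igfbp5 difference did not pass this test (1.23 in muscle against 0.80 in bone in the authors' deposited table, p = 0.753). That test does not show that the effects are alike, since low bone levels leave wide errors. Muscle control and bone control were not compared.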

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

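The tests in this part were chosen after the results were seen, apart from the erythroid list test in muscle, which kept a planned list and threshold. The comparison of the tissues drew attention to 3 lists that differed between muscle and bone in a test of the difference of the z values. A z value also depends on the error of a fold change, so equal fold changes with unequal errors could differ in this test. Fibrillar matrix genes were higher in muscle relative to bone (23 genes, adjusted p = 2.33e-07), with medians of 0.49 and -0.89. Matrix protease genes differed in the same direction (14 genes, adjusted p = 0.00328), with medians of 0.38 and -0.85. Erythroid genes differed in the opposite direction (5 genes, adjusted p = 0.00163), with medians of -0.99 in muscle and 0.99 in bone. With genes of a group mean of at least 50 in both tissues the adjusted p was 8.13e-09 for fibrillar matrix and 0.141 for matrix proteases. The erythroid list had fewer than 5 such genes and was not tested there. Most of its members were globin genes, which may vary together, so its p here can also be too small.

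In muscle, Igfbp5 and Col1a2 were higher in the knockout, and so were fibrillar matrix genes as a list. A lower share of red blood cells or muscle fibres is argued against, although erythroid genes were lower (median -0.99, cameraPR adjusted p = 5.98e-05). The listed erythroid and myofibre genes made up 0.362% of the summed larger group means. The matrix median needs a loss of 27.7% of control RNA and Igfbp5 of 57.3%. The listed genes leave out other RNA of these cells, so the argument holds only if they carry a large part of it. A lower share of other cells stays open, since the 8 progenitor genes with a group mean of at least 100 were all higher (median 0.24) and the 22 matrix genes of that level did not exceed them detectably (median 0.48, exact permutation p = 0.303, genes not being independent). A trend with expression level is argued against, since 4 of 10000 matched random lists reached the median of the matrix list. Loss of Esr1 remains a hypothesis, untested against the mixed control genotypes.

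In bone, most genes were higher in the knockout, and the skew lay at low group means. Genes with a group mean of at least 100 had a median of 0.0322, with an upper 95% bootstrap bound of 0.142. The authors' normalization is not given in the sources used here and can itself set that median near 0. A rise of all transcripts by the same factor would not by itself give medians of 7.63 at group means above 5 to 10 and -0.50 above 50 to 100. Low genes going undetected in more of the control libraries, with or without such a rise, and a rise limited to low transcripts both stay open. Depth per sample was not used here, and an effect of Esr1 loss was not tested.

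Also in bone, neutrophil genes were higher in the knockout. A rise of all marrow blood cells by the same factor is argued against as the whole cause, because the 7 neutrophil and 8 erythroid genes with a group mean of at least 100 moved apart (medians 3.06 and 0.78, exact permutation p = 0.00311, genes not being independent). More white cells or more of their RNA in the knockout samples stays open, since the 4 macrophage genes of that level were all higher (median 2.17), while Elane had 0.07 in the authors' deposited table, and the neutrophil genes themselves cannot test it. Per the labels the gate excluded CD45+ cells. Yet Ptprc, the gene of CD45, ranked 3170 by larger group mean in bone, above Pdgfra at 5391. Whether whole neutrophils or only RNA released from them reached the samples was therefore not settled. A change within neutrophils, or an effect of Esr1 loss on the marrow, was not tested.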

How the results depend on the processing

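The alternatives at FDR 0.1, with a fold change limit, by Spearman and at group means of at least 20 were planned, the last on another unit; the others, and the test of the tissue difference itself, were chosen after seeing the data. In muscle the count of 9 called genes fell to 4 by Bonferroni and to 6 over all genes with a p, where E2f5 (0.0521), Lars2 (0.0697) and L1cam (0.0800) no longer passed, and the Igfbp5 p became 0.166 by that adjustment; over all genes with a p it was 0.0332 and over genes with a group mean of at least 50 it was 0.00794. In bone the count of 3 became 2751 at FDR 0.1, 1 by Bonferroni and 10 over genes with a group mean of at least 50, where fewer genes were tested. Of 8 muscle lists past the threshold, 1 of which is not described here, 2 remained past it at a preset correlation of 0.05 (fibrillar matrix and erythroid); 2 were past it with all genes that have a p and 2 against matched random lists. The count of genes whose effect differed between tissues went from 0 to 12 at FDR 0.1. The correlation of 0.0161 was 0.0255 by Spearman, 0.00159 at group means of at least 20 and 0.0199 with an FDR in both. Esr1 in both tissues and Igfbp5 in bone passed under no setting run. The cause of these changes was not tested unless stated. No paired analysis was possible because the usable columns carry no replicate numbers. For the same reason other normalizations, count tools, count filters, unique reads, a joint fit of 12 samples, leaving out each replicate (the controls of differing genotype included), an estimated list correlation, fry, muscle control against bone control, and other splits of the samples were not run. Depth was not used here.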

Other observations

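The tests in this part were chosen after seeing the data, apart from those of the fixed lists. Among 1471 gene ontology terms tested in muscle, collagen fibril organization was higher in knockout samples (37 genes, median log2 fold change 0.59, cameraPR adjusted p = 0.000202), as was extracellular matrix organization (88 genes, median 0.47, adjusted p = 0.000483). Mitochondrial respiratory chain complex I assembly was lower (48 genes, median -0.36, adjusted p = 0.0488). Its call was lost with genes of a group mean of at least 50 (33 genes, adjusted p = 0.0926). The fixed oxidative phosphorylation list did not pass (30 genes, median -0.13, adjusted p = 0.336). In bone no term passed among 1666 (smallest adjusted p = 0.996). With genes of a group mean of at least 50, 310 terms were tested. Of these, 7 passed. Defense response to Gram-positive bacterium was higher (15 genes, adjusted p = 0.000410), as were the terms for bacterium (18 genes, 0.00143), Gram-negative bacterium (14 genes, 0.00236), chemotaxis (18 genes, 0.0118), cytoplasmic translation (77 genes, 0.0221) and response to lipopolysaccharide (17 genes, 0.0414). Steroid metabolic process was lower (10 genes, median -2.44, adjusted p = 0.0221). Members shared with the neutrophil list were not removed from the antibacterial terms. Members shared with the fibrillar matrix list were not removed from the muscle collagen and extracellular matrix terms. Neither set of terms is therefore separate evidence.

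Fabp4 and Pparg, genes of fat cells, had negative values in both tissues at an unadjusted p under 0.05. Fabp4 did not pass the authors' FDR in either tissue. Pparg did not pass in bone and had no FDR in muscle. Fabp4, a fatty acid binding protein gene, had -1.65 in muscle (p = 0.00234) and -6.95 in bone (p = 0.00281) in the authors' deposited table. Pparg, the adipogenic nuclear receptor gene, had -4.43 in muscle (p = 0.0394) and -5.29 in bone (p = 0.0385) in the authors' deposited table, at larger group means of 18.3 and 8.54. Both belong to the 22 genes lower in both tissues, a number not beyond chance (16.1 expected, exact hypergeometric p = 0.0835). Other members of the fixed adipogenic list were mixed, with Lpl at 0.83 in muscle (p = 0.0214) and Adipoq at -6.43 in muscle (p = 0.0434) and 2.25 in bone (p = 0.131) in the authors' deposited table. That list did not pass in muscle (8 genes, adjusted p = 0.388) or bone (10 genes, adjusted p = 0.244).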
